A study of Homo sapiens with 6 samples.

How the data were processed

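Poly-A RNA sequencing was used to profile the human breast cancer line MDA-MB-231 after 2 h with the vehicle DMSO or with 2 µM of H182, a compound that the series title places among small-molecule inhibitors of the transcription factor STAT3. The data comprised 3 DMSO libraries and 3 H182 libraries. Per the labels' protocols, RNA was isolated with a column kit, and libraries were made with a stranded Illumina kit after poly-A selection. Per the submitters' processing notes, STAR 2.5.0, RSEM 1.2.25 and the build GRCh38 were used. The gene annotation, any trimming and the strand setting of the counting were not given in the sources used here.

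The deposited values were TPM per gene and library, as the authors' table gave them, rounded to 2 decimals. RSEM divides estimated reads by transcript length and scales each library to 1000000, so a gene's TPM is its share of the library, and a large rise of some transcripts lowers the share of all others. TPM keeps no record of the number of reads, so the depth of each library is unknown, and no counting interval or detection limit was given. The table held 27567 rows. Of these, 92 were spike-in rows listed at 0 in every library, and 24 were second rows for genes shared by the X and Y chromosomes with the same values as their X rows. Both kinds were left out, which left 27451 gene rows. By gene identifier, 26943 of these matched the GENCODE 29 annotation of GRCh38, 22793 with the same version number. Coordinates, gene types, exon numbers and GC content were taken from that annotation.

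Values were analysed as log2(TPM + 1), with a pseudocount of 1, for the 12294 genes with a mean of at least 1 TPM over the 6 libraries. Fold changes on this scale understate the change of lowly expressed genes, so ratios of mean TPM are given beside them. H182 was compared with DMSO with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A size threshold of 1 on the log2 scale marked changes of at least 2-fold. The verbs rose and fell are used for genes that passed the adjusted threshold. Every adjusted p-value of a single gene comes from this limma fit. Errors are SDs over 3 libraries unless called SE. Labels give no account of whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical. The exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1.

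There were 26 gene lists for pathways and complexes, and 4 lists of markers of other cell types, fixed before the data were examined. Members were matched by symbol, with older symbols allowed. For the 62 symbols with more than 1 gene identifier, the identifier with the highest mean was used. Each pathway list was tested against all other genes with camera in limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 26 lists. Camera with an estimated correlation, camera on ranks and fry were run as alternatives, and fry in one direction is meant unless stated. Fry tests a list against no change and not against other genes, so a shift of all TPM values enters its result. Counts of members adjusted over the list alone used the same p-values with adjustment within the list. Genes were named by a rule fixed before the data were examined: 10 genes fixed by name, the 8 genes with the largest rise and the 8 with the largest fall among those passing with non-overlapping groups, and up to 4 members of each list with the lowest p among those passing. Where no member of a list passed, the 2 with the lowest p were named. A few of the genes so chosen are not reported here. Readthrough loci and unnamed clones were skipped among the largest changes. Other members named to describe a list were chosen after their values were seen.

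The test was run on simulated data first, with known changes added to values drawn for the 12294 genes at the spread of the real libraries. In 10 simulations it called 17.4% of the genes changed by 0.25 on the log2 scale, 59.8% at 0.5, 89.6% at 1 and 98.0% at 2. Of its calls, 4.40% were unchanged genes. Few genes were changed in each simulation, up or down at random. These rates therefore do not cover a shift of most genes by rescaling to a fixed total, as the real libraries can have. All 20 simulated lists shifted by 0.5 were called, and none of 500 unshifted lists, with genes simulated as independent.

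Alternatives covered the pseudocount, the filter on low values, median-of-ratios scaling of the TPM, quantile normalization, the variance model, library weights, a replicate block, the threshold, the kind of list test, and leaving out each library in turn. An alternative in which each library's total was taken without HSPA1A, HSPA1B and DNAJB1 was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.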

Results

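Gene expression was measured by RNA sequencing in MDA-MB-231, an established human breast cancer line that lacks the estrogen and progesterone receptors, after 2 h with DMSO (3 libraries) or with 2 µM of H182 (3 libraries). Values were TPM scaled to 1000000 per library, so depth was unknown. Between 10753 and 11306 rows were listed at 0 per library, and between 12230 and 12353 genes reached 1 TPM. Over the tested genes, libraries of the same group correlated at r = 0.9928 to 0.9942 across genes, and libraries of different groups at 0.9787 to 0.9806. Genes are not independent replicates. The first principal component held 65.2% of the variance and separated the groups.

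The comparison of H182 with DMSO asked which transcripts had changed 2 h after the compound was added. Among the genes chosen by the naming rule, the heat shock genes HSPA6, HSPA1A and HSPA1B rose most. HSPA6, an inducible HSP70, went from 1.70 ± 0.0551 TPM in DMSO to 1003 ± 53.1 TPM in H182 (SD, n = 3 each), and its cochaperone gene DNAJB1 from 238 ± 16.3 to 5589 ± 184 TPM. HMOX1, the heme-degrading enzyme heme oxygenase, rose 47.2-fold, and DDIT4, an inhibitor of mTORC1 signalling, rose 46.8-fold. Of the measured list members, 26 of 33 immediate early genes rose and 4 fell. Of NF-kappaB targets and cytokines 10 of 23 rose and 2 fell, and of cholesterol genes 9 of 21 rose and none fell. The endoplasmic reticulum list changed only in part, with 9 of 30 members higher and 3 lower. Among all 12294 tested genes, 651 rose and 2304 fell. Genes of the G2 and M phases of the cell cycle fell by less than 2-fold. STAT3 mRNA was at 64.8 ± 1.35 TPM in DMSO and 63.9 ± 0.847 TPM in H182.

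Of 12294 tested genes, 2955 differed at an adjusted p under 0.05, 651 higher and 2304 lower in H182, so that 78.0% of the calls were lower. At least 2-fold changes were mostly rises, with 160 genes higher and 26 lower, and at least 4-fold changes were 57 higher and 1 lower. In TPM the groups did not overlap in 5085 genes, 41.4% of those tested, where chance gives 10%. Of these, 2942 passed, 648 higher and 2294 lower. A shift of most genes by rescaling can add to this count, which was not taken with another scaling. The split between higher and lower calls depended on the scaling. The median change of the tested genes was -0.09 on the log2 scale in TPM and 0.00 with median-of-ratios scaling, which moved lowly expressed genes by less. With that scaling 969 genes were higher and 833 lower (46.2% lower), and with quantile normalization 833 were higher and 1261 lower (60.2% lower). The genes raised at least 2-fold held 1.17 ± 0.0182% of all TPM in DMSO and 6.25 ± 0.114% in H182. For each list, counts with median-of-ratios scaling are therefore given beside those in TPM.

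**Figure D1:**
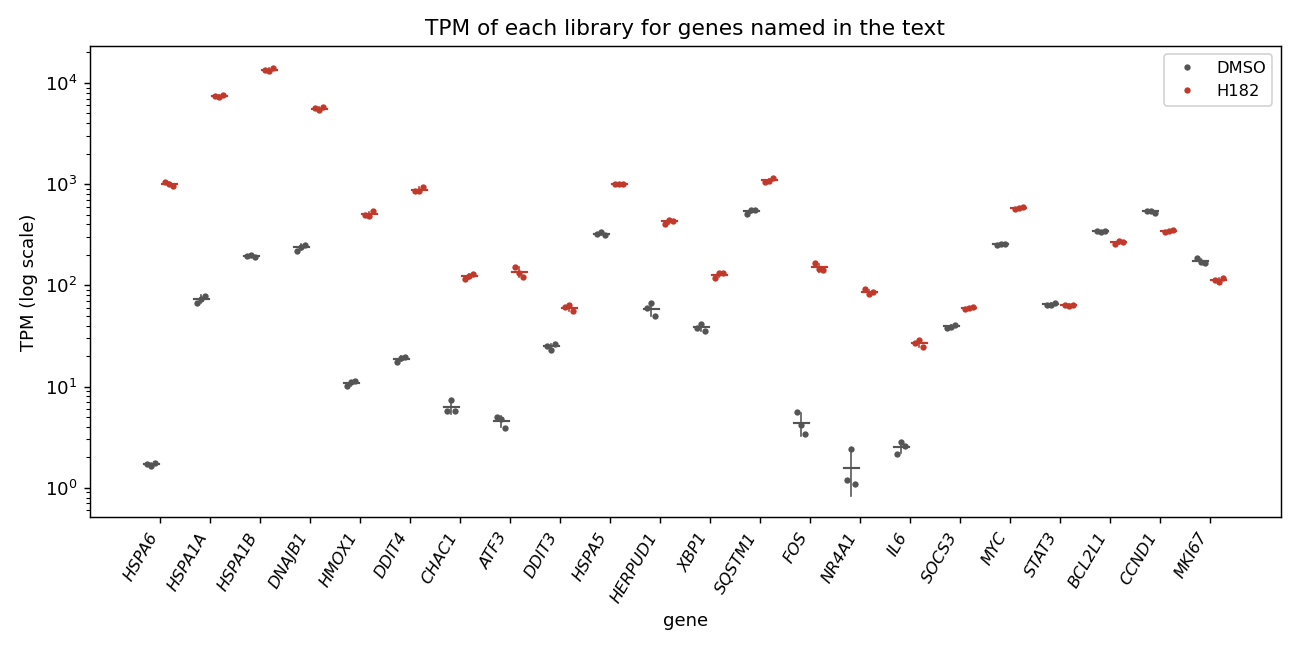
TPM of each library (vertical axis, log scale) for 22 named genes (horizontal axis). Points are the 3 DMSO (grey) and 3 H182 (red) libraries, horizontal lines their means and vertical lines 1 SD. HSPA6 lies at 1.70 TPM in DMSO and 1003 TPM in H182, while STAT3 lies at 64.8 and 63.9 TPM.

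The cytosolic heat shock list, chaperones and cochaperones that handle unfolded proteins, rose as a group. Of its 30 measured members, 25 rose and none fell (26 and 0 adjusted over the list alone; 27 and 0 with median-of-ratios scaling), 15 of them at least 2-fold. Camera called the list higher (adjusted p = 4.11e-51; adjusted p = 0.0208 with an estimated correlation). HSPA6 (ENSG00000173110.7, chromosome 1, 161524540 to 161526910, GRCh38, plus strand, 1 exon) changed by 8.54 on the log2 scale (SE 0.056, adjusted p = 1.69e-13), a 591-fold ratio of mean TPM. HSPA1A (ENSG00000204389.9, chromosome 6, 31815464 to 31817946, plus strand, 1 exon) went from 73.4 ± 6.03 to 7492 ± 153 TPM, and HSPA1B (ENSG00000204388.6, chromosome 6, 31827735 to 31830255, plus strand, 1 exon) from 194 ± 5.43 to 13549 ± 515 TPM. These neighbouring copies are near-identical, so the division of reads between them is uncertain. Their sum rose 78.7-fold, from 267 ± 5.92 to 21041 ± 664 TPM. Reads of HSPA6 can likewise be shared with its pseudogene HSPA7. DNAJB1, the HSP40 that delivers clients to HSP70, rose 23.5-fold (log2 change 4.55, adjusted p = 6.14e-12). HSPA1A, HSPA1B and DNAJB1 together took 0.0505 ± 0.00208% of all TPM in DMSO and 2.66 ± 0.0841% in H182.

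Other members of the heat shock list rose less. HSPH1, a nucleotide exchange factor of the HSP110 family, changed by 2.57, the cochaperone BAG3 by 2.54, the small heat shock protein HSPB1 by 2.24, HSP90AA1 by 1.41 and the constitutive HSPA8 by 1.11 on the log2 scale. The members that did not pass were FKBP5 (-0.06), PTGES3 (-0.01), CDC37 (0.00), ST13 (0.08) and DNAJB6 (0.14).

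The endoplasmic reticulum list, which holds chaperones and degradation factors of the ATF6 and XBP1 arms of the unfolded protein response, changed in part. Of 30 measured members, 9 rose, 3 fell and 18 did not pass (11 and 3 adjusted over the list alone; 17 and 1 with median-of-ratios scaling). It was called higher at the preset correlation (camera adjusted p = 2.40e-08) and not with an estimated one (adjusted p = 0.117). HSPA5, the lumenal HSP70 BiP (ENSG00000044574.7, chromosome 9, 125234853 to 125241330, minus strand, 8 exons), rose from 324 ± 10.9 to 1001 ± 8.54 TPM (log2 change 1.62, SE 0.035, adjusted p = 1.19e-09). HERPUD1, a component of endoplasmic reticulum associated degradation, rose 7.33-fold from 58.3 ± 8.78 TPM, the transcription factor XBP1 rose 3.34-fold from 38.3 ± 3.16 TPM, and the cochaperone DNAJB9 rose 4.27-fold from 9.05 ± 3.03 TPM. Among the lectin chaperones and disulfide isomerases, CALR (0.09), CANX (-0.09), PDIA4 (0.06) and PDIA6 (-0.05) did not pass. The members that fell were WFS1 (-0.40), EDEM1 (-0.28) and DERL1 (-0.20). Gene-level TPM does not distinguish spliced from unspliced XBP1 mRNA.

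The next list holds targets of ATF4 and CHOP, the transcription factors of the integrated stress response. Of 30 measured members, 17 rose, ATF5 (-0.24) and XPOT (-0.15) fell and 11 did not pass (21 and 3 adjusted over the list alone; 21 and 0 with median-of-ratios scaling), and 9 rose at least 2-fold. The list was called higher (camera adjusted p = 3.48e-20; adjusted p = 0.0453 with an estimated correlation). DDIT4 (ENSG00000168209.4, chromosome 10, 72273920 to 72276036, plus strand, 3 exons) rose from 18.9 ± 1.04 to 882 ± 51.4 TPM (log2 change 5.48, SE 0.056, adjusted p = 4.67e-12). ATF3, a stress-induced transcription factor (chromosome 1, 212565334 to 212620777, plus strand, 4 exons), rose from 4.56 ± 0.608 to 136 ± 14.7 TPM. CHAC1, a glutathione-degrading enzyme, rose 19.6-fold from 6.25 ± 0.922 TPM, and SESN2, a leucine sensor that restrains mTORC1, rose 10.9-fold from 7.39 ± 0.429 TPM. DDIT3, the gene of CHOP (chromosome 12, 57516588 to 57521737, minus strand, 4 exons), rose 2.41-fold from 24.9 ± 1.68 TPM (log2 change 1.23, adjusted p = 2.73e-06). ASNS, asparagine synthetase, changed by 0.90, while PSAT1, SHMT2 and GARS, at 0.13, 0.01 and 0.12, did not pass.

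Of 25 measured NRF2 target genes, which act in defence against oxidants, 13 rose and none fell (13 and 0 adjusted over the list alone and with median-of-ratios scaling). The call of the list as higher (camera adjusted p = 2.20e-12) did not hold with an estimated correlation (adjusted p = 0.0605). HMOX1 (ENSG00000100292.16, chromosome 22, 35380361 to 35394214, plus strand, 5 exons) rose from 10.8 ± 0.635 to 508 ± 26.9 TPM (log2 change 5.44, SE 0.059, adjusted p = 6.11e-12). The ferritin chains FTL and FTH1 rose 1.78-fold and 1.69-fold from 1780 ± 25.7 and 1497 ± 14.6 TPM. SQSTM1, the autophagy receptor p62 (chromosome 5, 179806398 to 179838078, plus strand, 8 exons), rose from 541 ± 25.5 to 1091 ± 41.6 TPM. The glutathione synthesis genes GCLM (0.80) and GCLC (0.55) also rose on the log2 scale. PGD (-0.08) and TKT (-0.04), of the pentose phosphate pathway, did not pass. Of 6 measured metallothionein and zinc export genes, MT1X rose by 0.69 and MT1E by 0.26 on the log2 scale, and the other 4 did not pass (2 and 0 adjusted over the list alone; 3 and 0 with median-of-ratios scaling). That list was called higher (camera adjusted p = 0.00298; adjusted p = 0.109 with an estimated correlation and 0.0522 by fry).

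The series title concerns STAT3 inhibitors, so STAT3 and a list of its pathway and target genes were examined. The list also holds STAT3 itself and upstream cytokine, receptor and kinase genes such as IL6, IL6ST and JAK1, so it is not a set of targets alone. STAT3 (ENSG00000168610.14, chromosome 17, 42313324 to 42388568, minus strand, 24 exons) did not differ detectably between the groups (log2 change -0.02, SE 0.046, limma adjusted p = 0.779; two-sided exact permutation p = 0.5, smallest possible 0.1). Its change was 0.08 with median-of-ratios scaling, which did not pass either. The mRNA level says nothing about the phosphorylation or activity of the protein. Of 28 measured members of the list, 13 rose and 5 fell (14 and 6 adjusted over the list alone; 13 and 5 with median-of-ratios scaling), and it was called higher (camera adjusted p = 1.10e-07; adjusted p = 0.0386 with an estimated correlation). Several of the genes that rose are also immediate early or stress genes and are not specific to STAT3: FOS rose 34.4-fold from 4.36 ± 1.11 TPM, IL6 10.6-fold from 2.52 ± 0.331 TPM, CEBPB 4.05-fold from 70.5 ± 3.52 TPM and MYC 2.27-fold from 256 ± 3.70 TPM. SOCS3, the feedback inhibitor of cytokine signalling (chromosome 17, 78356778 to 78360077, minus strand, 2 exons), rose from 39.2 ± 1.68 to 59.7 ± 1.55 TPM (log2 change 0.59, adjusted p = 6.03e-05). The members that fell were CCND1, the gene of cyclin D1 (from 537 ± 14.9 to 346 ± 8.07 TPM), BCL2L1, which encodes the survival factor BCL-XL (from 341 ± 3.97 to 265 ± 6.62 TPM), IRF1 (-0.49), LIF (-0.49) and BIRC5, the gene of survivin (-0.30). The survival gene MCL1 rose from 188 ± 8.99 to 350 ± 17.5 TPM. The receptor and kinase genes IL6ST (-0.13), JAK1 (-0.07) and JAK2 (0.38) did not pass.

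Immediate early genes, which respond to signals without new protein synthesis, showed 26 rises and 4 falls among 33 measured members (27 and 4 adjusted over the list alone and with median-of-ratios scaling), with 20 rises of at least 2-fold. As a group they were called higher (camera adjusted p = 2.05e-34; adjusted p = 0.0208 with an estimated correlation). The orphan nuclear receptor genes NR4A1 and NR4A2 rose 55.5-fold from 1.56 ± 0.734 TPM and 48.1-fold from 2.19 ± 0.405 TPM. DUSP1, a phosphatase of MAP kinases (ENSG00000120129.5, chromosome 5, 172768090 to 172771195, minus strand, 4 exons), rose from 23.1 ± 1.01 to 783 ± 18.1 TPM (log2 change 5.03, SE 0.045, adjusted p = 1.58e-12). EGR1 rose 12.3-fold from 9.84 ± 0.219 TPM and IER5 5.98-fold from 57.5 ± 3.26 TPM. The falls were FOSL1 (-0.87), KLF10 (-0.82), DUSP6 (-0.77) and DUSP4 (-0.31), of which DUSP4 and DUSP6 are feedback phosphatases of ERK. Of 23 measured NF-kappaB targets and cytokines, 10 rose and 2 fell (10 and 2 adjusted over the list alone; 11 and 1 with median-of-ratios scaling), and the list was called higher (camera adjusted p = 2.40e-08; adjusted p = 0.0463 with an estimated correlation). The neutrophil chemokine CXCL8 rose 6.61-fold from 11.1 ± 0.666 TPM, CXCL2 14.2-fold from 1.29 ± 0.630 TPM and the cytokine IL11 3.45-fold from 98.7 ± 5.25 TPM. The pathway's own inhibitor gene NFKBIA (0.14), as well as ICAM1 (-0.13) and SOD2 (-0.11), did not pass.

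**Figure D2:**
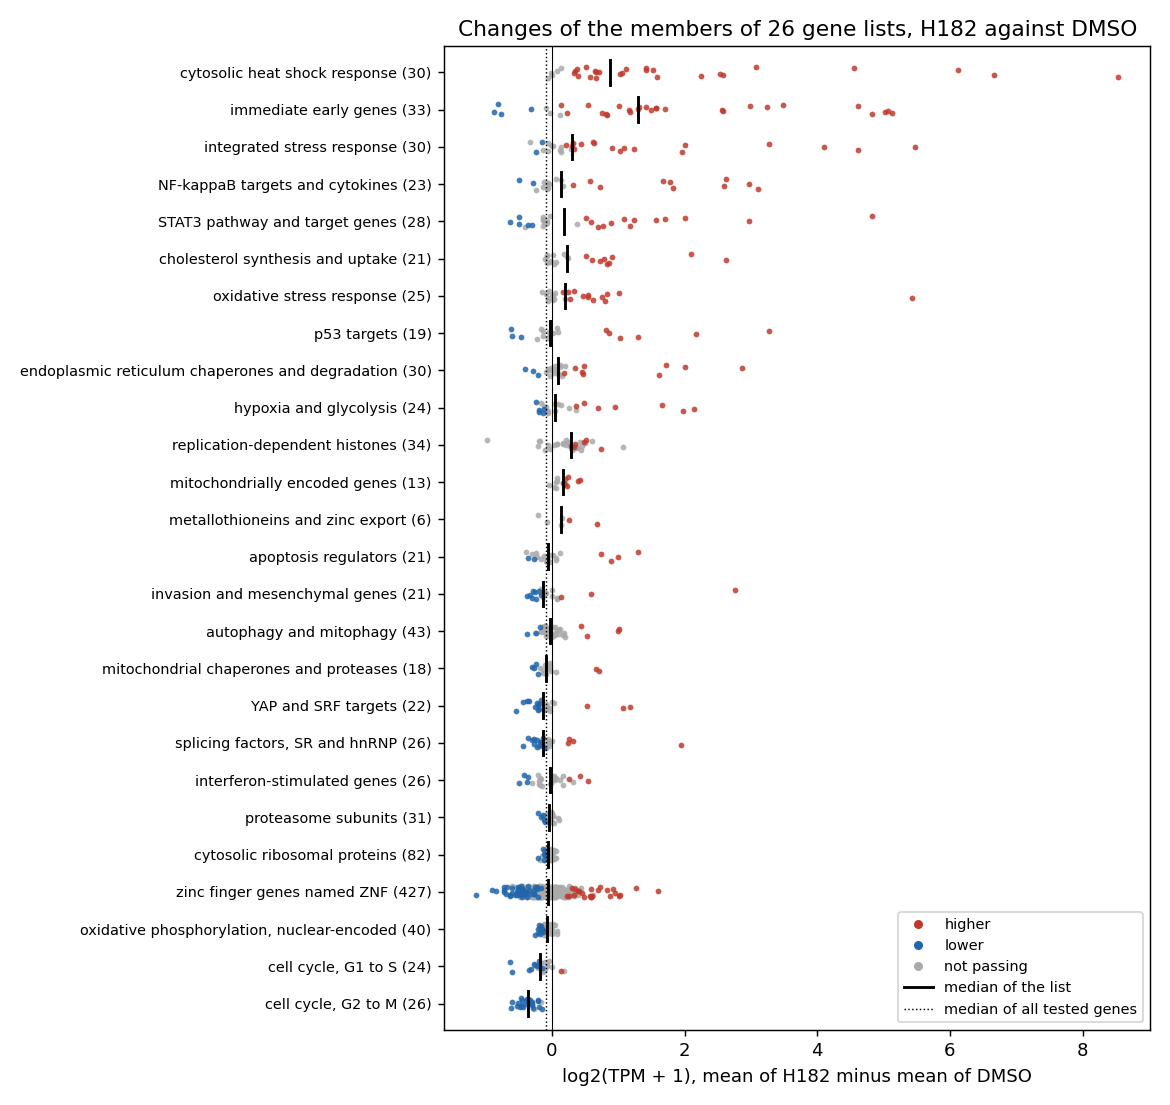
Change of each measured member (horizontal axis, mean log2(TPM + 1) in H182 minus that in DMSO) of the 26 gene lists (vertical axis, number of measured members in brackets), with lists in order of their mean change. Points are genes, coloured by their call, black bars are list medians and the dotted line is the median of all tested genes (-0.09). The heat shock list reaches 8.54 for HSPA6, and the G2 to M list lies at a median of -0.36.

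Of 43 measured autophagy and mitophagy genes, 4 rose, 3 fell and 36 did not pass (4 and 3 adjusted over the list alone; 7 and 0 with median-of-ratios scaling). The list was not called in TPM (camera adjusted p = 0.0588, and 0.514 with an estimated correlation). At the preset correlation it was called higher with median-of-ratios scaling (adjusted p = 0.00794) and with quantile normalization (0.00856). It was also called higher at a mean of at least 5 TPM, and without DMSO replicate 1, DMSO replicate 2 or H182 replicate 1. The 4 that rose were SQSTM1, the ATG8 family genes GABARAPL1 (2.11-fold from 8.67 ± 0.818 TPM) and MAP1LC3B (1.46-fold from 45.9 ± 1.66 TPM), and the kinase gene ULK1 (log2 change 0.45). ATG16L1 fell in TPM (log2 change -0.38, adjusted p = 0.0269) but did not pass with median-of-ratios scaling (-0.28), and the other falls were in the fusion genes MFN1 (-0.25) and MFN2 (-0.18), likewise lost with that scaling. The mitophagy genes PINK1 (-0.12), BNIP3 (0.04), BNIP3L (-0.11) and FUNDC1 (-0.13) did not pass.

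Of 18 measured mitochondrial chaperones and proteases, 2 rose and 4 fell (2 and 4 adjusted over the list alone; 2 and 1 with median-of-ratios scaling), and the list was not called (camera adjusted p = 0.898). HSPD1 and HSPE1, the HSP60 and HSP10 genes, rose 1.63-fold and 1.58-fold from 424 ± 9.56 and 270 ± 13.7 TPM, and both are also in the heat shock list. AFG3L2 fell to 0.813 of its DMSO level, and TOMM20 to 0.825, a call lost with median-of-ratios scaling. Of 13 mitochondrially encoded genes, 7 rose and none fell (8 and 0 adjusted over the list alone; 11 and 0 with median-of-ratios scaling), and their share of TPM was 4.25 ± 0.0871% in DMSO and 4.63 ± 0.144% in H182. The list was called higher (camera adjusted p = 3.42e-09; adjusted p = 0.0870 with an estimated correlation), but not with quantile normalization (adjusted p = 0.387). MT-ND6 rose 1.35-fold, MT-ND5 1.31-fold, MT-CYB 1.19-fold and MT-ND4 1.17-fold. MT-ND6 lies on the strand opposite MT-ND5, and the strand setting of the counting is not known, so their values may share reads. Of 40 nuclear genes of oxidative phosphorylation, none rose and 10 fell in TPM (0 and 10 adjusted over the list alone), but only 1 fell with median-of-ratios scaling. The list was not called in TPM (camera adjusted p = 0.213) but was called lower without a filter on low values (adjusted p = 0.0256) and without H182 replicate 1 (0.0174). Fry, which tests against no change, called it lower in TPM (adjusted p = 0.0453), although its median lay 0.0208 above that of all tested genes. ATP5A1 fell by 0.26 on the log2 scale and passed with both scalings, while the falls of ATP5C1 (-0.19), ATP5F1 (-0.17) and NDUFS1 (-0.21) in TPM did not pass with median-of-ratios scaling.

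Genes of the G2 and M phases fell as a group. Of 26 measured members, 24 fell and none rose (25 and 0 adjusted over the list alone; 20 and 0 with median-of-ratios scaling), none by 2-fold, and the list median was -0.36, or -0.27 relative to the median gene. Camera called it lower (adjusted p = 6.66e-13; adjusted p = 0.0317 with an estimated correlation). The proliferation marker MKI67 fell from 174 ± 9.71 to 113 ± 5.93 TPM, the mitotic kinesin KIF23 from 114 ± 4.04 to 74.5 ± 1.88 TPM, cyclin A2 (CCNA2) from 149 ± 0.686 to 105 ± 4.24 TPM and topoisomerase TOP2A from 343 ± 11.3 to 252 ± 4.84 TPM. Of 24 measured genes of the G1 to S transition, 1 rose and 10 fell (1 and 15 adjusted over the list alone; 1 and 5 with median-of-ratios scaling), and the list was called lower (camera adjusted p = 0.00361; adjusted p = 0.284 with an estimated correlation). The falls with the lowest p were those of CCND1, to 0.644 of its DMSO level, the replication genes MCM4 (0.802) and MCM3 (0.854) and the DNA methylation cofactor UHRF1 (0.788). Replication-dependent histone genes, whose mRNAs mostly lack poly-A tails and are poorly captured by poly-A selection, showed 6 rises and no fall among 34 measured members (5 and 0 adjusted over the list alone; 8 and 0 with median-of-ratios scaling). That list was called higher (camera adjusted p = 1.32e-07; adjusted p = 0.0215 with an estimated correlation), with HIST1H2BK up 1.22-fold from 344 ± 4.97 TPM, HIST1H2AC 1.30-fold from 14.6 ± 0.554 TPM, HIST1H2BD 1.27-fold from 23.9 ± 2.23 TPM and HIST2H3D 1.85-fold from 3.30 ± 0.891 TPM. These genes are similar in sequence, so reads can be shared among them.

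Among 19 measured p53 targets, 6 rose and 3 fell (6 and 4 adjusted over the list alone; 6 and 3 with median-of-ratios scaling). The cell cycle inhibitor CDKN1A rose from 46.3 ± 0.363 to 212 ± 9.59 TPM, SESN2 as above, GADD45A 1.78-fold and the BH3-only gene BBC3 2.92-fold from 3.15 ± 0.444 TPM. MDM2 (-0.03), BAX (-0.17) and FAS (-0.22) did not pass, and ZMAT3 (-0.61), XPC (-0.61) and AEN (-0.46) fell. The list was called higher at the preset correlation (camera adjusted p = 0.00151; adjusted p = 0.160 with an estimated correlation and 0.125 on ranks), although its median change was -0.03 and its mean 0.38. Of 21 apoptosis regulators, 4 rose and 2 fell (4 and 5 adjusted over the list alone, and 5 and 1 with median-of-ratios scaling). The list was not called (camera adjusted p = 0.0858), though camera called it higher at a mean of at least 5 TPM (adjusted p = 0.0475) and without H182 replicate 1 (0.0474). Fry, against no change, also called it higher (adjusted p = 0.0398). The rises were MCL1, BBC3, BCL2L11 and PMAIP1, the last from 52.3 ± 0.899 to 105 ± 2.17 TPM, and BCL2L1 fell.

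Cholesterol synthesis and uptake genes, targets of SREBP2, showed 9 rises and no fall among 21 measured members (9 and 0 adjusted over the list alone; 10 and 0 with median-of-ratios scaling). Camera called this list higher (adjusted p = 2.19e-11; adjusted p = 0.0215 with an estimated correlation). INSIG1, which retains SREBP in the endoplasmic reticulum, rose from 31.3 ± 2.23 to 199 ± 8.75 TPM, the synthase HMGCS1 from 17.1 ± 0.781 to 76.3 ± 4.81 TPM and IDI1 1.89-fold. Of 24 measured HIF1 targets, 7 rose and 5 fell (8 and 5 adjusted over the list alone; 9 and 0 with median-of-ratios scaling), and the call as higher (camera adjusted p = 0.000297) did not hold with an estimated correlation (adjusted p = 0.243) or on ranks (0.0754). The vasodilator peptide gene ADM rose 3.16-fold from 203 ± 0.476 TPM, the glucose transporter SLC2A3 4.77-fold, ANKRD37 4.29-fold and PFKFB3, a regulator of glycolysis, 1.95-fold, while the glycolytic genes HK2 (-0.24), ENO1 (-0.19), PFKP (-0.14) and ALDOA (-0.11) fell in TPM and not with median-of-ratios scaling.

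Of 22 measured YAP and SRF targets, 3 rose and 11 fell (3 and 11 adjusted over the list alone; 3 and 5 with median-of-ratios scaling), and the list was not called in TPM (camera adjusted p = 0.182) but was called lower without a filter on low values (adjusted p = 0.0382), with quantile normalization (0.0435) and on ranks (0.0287). The matricellular genes CTGF and CYR61 rose 2.27-fold and 2.09-fold from 775 ± 0.458 and 1117 ± 7.08 TPM, whereas ANKRD1 and the tissue factor gene F3 fell to 0.773 and 0.743 of their DMSO levels. Of 21 invasion and mesenchymal genes, 3 rose and 8 fell (3 and 10 adjusted over the list alone; 3 and 5 with median-of-ratios scaling), without a call of the list (camera adjusted p = 0.542). SNAI1, a repressor of E-cadherin, rose from 0.710 ± 0.207 to 10.5 ± 1.02 TPM and SERPINE2 rose 1.53-fold, while the urokinase gene PLAU and the integrin gene ITGB1 fell to 0.771 and 0.814 of their DMSO levels. Of 26 splicing factor genes, 4 rose and 15 fell (4 and 17 adjusted over the list alone; 4 and 6 with median-of-ratios scaling). The kinase CLK1 rose 3.96-fold from 31.9 ± 2.23 TPM, and SRSF1, HNRNPD and HNRNPDL fell to 0.810, 0.830 and 0.783 of their DMSO levels. That list was called lower (camera adjusted p = 0.0447; adjusted p = 0.514 with an estimated correlation), although its mean change of -0.03 lay above the median gene. The call was lost with median-of-ratios scaling (adjusted p = 0.439), without a trend in eBayes (0.288), at a mean of at least 5 TPM (0.0929) and without DMSO replicate 2 or 3 or H182 replicate 2 or 3.

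Several lists showed little or mixed change. Of 26 interferon-stimulated genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; 4 and 3 with median-of-ratios scaling), with IRF1 and IFIT3 at 0.703 and 0.739 of their DMSO levels and IRF7 up by 0.55 on the log2 scale, and the list was not called (camera adjusted p = 0.253). Of 31 proteasome subunit genes, none rose and 5 fell in TPM (0 and 3 adjusted over the list alone), including PSMD2 (-0.16), PSMD1 (-0.20), PSMD3 (-0.14) and PSMC3 (-0.11), but with median-of-ratios scaling 3 rose and none fell. The list was not called by camera in TPM (adjusted p = 0.856) and was called higher with median-of-ratios scaling (adjusted p = 0.0167). Fry, which tests against no change, called it lower in TPM (adjusted p = 0.00228), although its median lay 0.0570 above that of all tested genes. Of 82 genes matched by their symbols as ribosomal protein genes, 6 fell in TPM and none with median-of-ratios scaling. Adjusted over the list alone, 1 fell, the ribosomal protein-like gene RPL7L1. The direction of this list turned with the scaling. It was not called in TPM (camera adjusted p = 0.533). At the preset correlation it was called higher with median-of-ratios scaling (adjusted p = 0.0136) and lower with quantile normalization (2.37e-07) and without H182 replicate 1 (0.000415). Its estimated correlation in TPM was 0.484, far above the preset, and with that it was not called (camera adjusted p = 0.897). RPL7L1, RPS6, RPL7 and RPS4X lay at -0.21, -0.11, -0.10 and -0.11. Of 427 zinc finger genes named ZNF, 24 rose and 51 fell (21 and 42 adjusted over the list alone; 34 and 26 with median-of-ratios scaling), without a call of the list (camera adjusted p = 0.0777), though it was called higher on ranks (adjusted p = 0.0287). ZNF844 rose 3.57-fold from 3.80 ± 0.527 TPM, ZNF44 2.10-fold from 5.73 ± 0.390 TPM and ZNF442 3.24-fold from 1.70 ± 0.288 TPM, while ZNF347 fell to 0.533 of its DMSO level.

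The largest falls were in genes of low or moderate level. DGAT2, the last enzyme of triglyceride synthesis (ENSG00000062282.14, chromosome 11, 75759512 to 75801535, plus strand, 8 exons), fell from 8.47 ± 0.786 to 1.65 ± 0.301 TPM (log2 change -1.84, SE 0.13, adjusted p = 9.79e-06). NANOS1, a translational repressor, fell from 32.0 ± 2.61 to 11.8 ± 0.551 TPM, the decoy receptor gene TNFRSF10D from 36.5 ± 0.847 to 15.4 ± 0.890 TPM and the metalloprotease gene ADAMTS15 from 19.2 ± 0.839 to 7.91 ± 0.154 TPM. FABP4 fell from 3.01 ± 0.563 to 0.510 ± 0.613 TPM and LY6D from 2.01 ± 0.257 to 0.400 ± 0.693 TPM, with 1 of the 3 H182 libraries above 1 TPM for both, and LY6D lost its call without a filter on low values and without DMSO replicate 2, H182 replicate 1 or H182 replicate 2. NDUFA7 (31.7 ± 12.6 to 8.66 ± 4.95 TPM) and HYPK (8.86 ± 2.06 to 3.07 ± 1.36 TPM) varied between replicates and overlap neighbouring or readthrough loci, so the division of their reads is uncertain.

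Markers of other cell types gave levels of the culture itself. Of 8 tested luminal epithelial markers, CLDN4 rose 1.43-fold from 18.2 ± 0.955 TPM, GATA3 fell to 0.657 of its DMSO level, and KRT8 and KRT18, at 482 ± 5.51 and 466 ± 8.13 TPM in DMSO, fell by 0.17 and by 0.14 in TPM but not with median-of-ratios scaling. None of the 3 leukocyte, 3 fibroblast and 2 endothelial markers tested passed. CD68 was at 153 ± 6.74 and 140 ± 1.85 TPM and CD14 at 1.84 ± 0.643 and 1.61 ± 0.582 TPM. COL6A3 was at 9.13 ± 0.688 and 8.36 ± 0.787 TPM, PDGFRB at 1.41 ± 0.592 and 0.787 ± 0.395 TPM, KDR at 4.69 ± 0.422 and 3.84 ± 0.140 TPM and EGFL7 at 14.02 ± 1.76 and 15.1 ± 1.41 TPM in DMSO and H182.

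Across the 26 lists, camera called 16, 13 higher and 3 lower, at the preset correlation. With an estimated correlation it called 8. Those called higher were heat shock, integrated stress response, STAT3 pathway and target genes, immediate early genes, NF-kappaB targets, cholesterol synthesis and histones. The list called lower was G2 to M.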

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

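The alternative that takes totals without HSPA1A, HSPA1B and DNAJB1 was chosen after the results were seen. STAT3 passed the test under none of the settings, with changes from -0.03 to 0.08 on the log2 scale. Of the other 119 genes chosen by the naming rule, 99 kept their direction and side of the threshold in every setting that tested them, 19 lost their call in at least 1 setting and none reversed. The filter at 5 TPM tested 112 of them. Calls were lost by 15 genes with median-of-ratios scaling, PSMD2, RPS6, KRT8 and ATP5C1 among them, 12 with eBayes without trend, 9 without a filter and 4 to 10 when 1 library was left out. CD68 passed when DMSO replicate 3 was left out.

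The number of lower genes depended on the scaling. The 2955 changed and 2304 lower genes became 1802 and 833 with median-of-ratios scaling. Lower genes numbered 1261 with quantile normalization and 1497 with totals taken without HSPA1A, HSPA1B and DNAJB1, and these differences follow from the rescaling itself. With the stricter threshold of 0.01, 1436 genes changed and 998 were lower. The 26 genes lower by at least 2-fold became 47 with a pseudocount of 0.1, 15 with a mean of at least 5 TPM, which tests fewer genes, and 16 with median-of-ratios scaling. The counts of higher genes stayed within 1.5 times of 651 and 160 in every setting at the threshold of 0.05.

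Leaving out 1 library at a time gave 1947 to 2758 changed genes and 1396 to 2205 lower genes. The lowest values came without DMSO replicate 2, and 1478 genes were lower without H182 replicate 2. Fewer samples alone lower such counts.

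The camera calls depended on whether the correlation was preset or estimated, and the weaker p-values do not measure correlation alone. For the histone list the estimated correlation of -0.0184 lay below the preset of 0.01. Its camera adjusted p still went from 1.32e-07 to 0.0215. Of 16 lists called, 13 higher and 3 lower, an estimated correlation kept 8, 7 higher and 1 lower. Lists called lower numbered 5 without a filter on low values, 5 with quantile normalization and 5 with fry tested one way, and 2 to 5 when 1 library was left out, with 5 without H182 replicate 1 and 2 or 3 without any other library. Fry tested either way called 25 lists. The splicing factor list was called lower in TPM although its mean lay 0.02 above other genes, and with quantile normalization (adjusted p = 0.00679) this mean difference reversed to -0.01335. That call was lost in 8 other settings. The ribosomal protein list, not called by camera in TPM, turned direction with the scaling. The proteasome list, likewise not called by camera in TPM, was called higher by camera with median-of-ratios scaling. It was called lower in TPM by fry, which tests against no change and so asks another question.

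Replicate numbers did not pair the libraries: same-numbered libraries deviated together with correlations of -0.013, 0.00245 and -0.0359, and by these deviations no DMSO library correlated best with the H182 library of its own number. With a replicate block, 2684 genes changed, 625 higher and 2059 lower, the list calls stayed as they were, and 2 named genes lost their call. The unknown depth leaves the counting error of genes near 1 TPM open.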

Other observations

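The tests of displacement with totals taken without the raised genes, of exons and span without a limit on the change, and of runs of zinc finger genes of similar level, and the choice of the zinc finger cluster and of the genes in the next 2 paragraphs, came after the values were seen. H182 raised all 4 genes of the ID family, inhibitors of basic helix-loop-helix transcription factors, in TPM and with median-of-ratios and quantile scaling. ID2 rose 15.5-fold from 2.39 ± 0.835 TPM (SD, n = 3), ID4 7.02-fold from 13.9 ± 1.70 TPM, ID3 3.60-fold from 45.3 ± 2.36 TPM and ID1 3.27-fold from 91.7 ± 7.25 TPM. The nuclear long noncoding RNAs NEAT1 and MALAT1 rose 9.89-fold from 53.9 ± 6.90 TPM and 2.16-fold from 30.9 ± 0.640 TPM. CDKN1C, a cyclin-dependent kinase inhibitor outside the p53 list, rose from 4.38 ± 0.749 to 50.01 ± 3.23 TPM. The neuronal activity gene ARC rose 67.0-fold from 0.720 ± 0.252 TPM, RASD1, a glucocorticoid-inducible small GTPase, 21.0-fold, the G protein regulator RGS2 19.9-fold, the kinase gene SGK1 6.07-fold and TSC22D3, which encodes GILZ, 6.80-fold.

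The proteasome-associated stress gene ZFAND2A rose from 43.4 ± 4.05 to 366 ± 43.9 TPM, and the deubiquitinase gene OTUD1 from 12.3 ± 0.452 to 58.4 ± 0.792 TPM. HSF1, the main activator of heat shock genes, did not pass at 135 ± 7.81 and 130 ± 4.93 TPM, nor did NFE2L2, the gene of NRF2, at 81.3 ± 2.41 and 88.6 ± 9.10 TPM. Further cell cycle genes outside the lists fell: the anaphase-promoting complex inhibitor FBXO5 to 0.493 of its DMSO level, CCNF to 0.490, the centromere chaperone HJURP to 0.523 and E2F8 to 0.526. PCF11, a factor of mRNA 3' end cleavage, fell to 0.543, the nuclear phosphatase subunit PPP1R10 to 0.458 and SPRY1, a feedback inhibitor of receptor tyrosine kinases, to 0.433 of the DMSO level.

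On chromosome 19 between positions 11559374 and 12640098 (GRCh38), 9 of 25 tested ZNF genes rose and none fell, against 15 higher and 51 lower of 402 elsewhere, and the 9 were the same in number with median-of-ratios and quantile scaling. They were ZNF627, ZNF441, ZNF433, ZNF878, ZNF844, ZNF44, ZNF563, ZNF442 and ZNF490. Reads shared between similar genes are argued against as the cause, since the raised genes shared a median of 1.37% of their 50-base words with transcripts of other tested genes (8 of 9 under 5%, ZNF490 60.4%). A general rise of zinc finger genes at such low levels is argued against by a scan of runs of 5 to 50 neighbours over all chromosomes, in which the densest run was 24 genes of this cluster (permutation p = 0.000500, 10000 draws, calls permuted among genes of similar level). The draws treated the calls of neighbouring genes as independent, so this p shows that the rises lie together and measures no spread between libraries. A local response of this cluster to H182 may be a candidate explanation, as a hypothesis found and tested on the same libraries. Its mechanism was not tested.

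The genes raised at least 2-fold were short and had few exons: the 152 coding genes among them had a median span of 8.36 kb, 4 exons and 53.3% GC, and 11.8% had 1 exon, against medians over 1000 expression-matched lists of 31.2 kb, 9 exons, 48.7% GC (44.9 to 52.7%) and 2.63%. A general trend of the change on transcript length and GC content is argued against as the whole cause by its size. It moved coding genes by a median of 0.0139 and by at most 0.192. That 99.3% of the raised genes kept at least 2-fold without it, with a median of 1.66 after 1.68, follows from this small size. The fit gave little weight to outlying genes, so it could not show a bias confined to the raised genes. A general advantage of 1-exon genes is also argued against: among genes changed under 2-fold, 225 such genes differed from matched multi-exon genes by a median of -0.0967, and among all genes 248 differed by -0.0755. Multi-exon genes of the shortest spans differed from matched genes of the longest spans by a median of 0.00238 (997 pairs) under that limit and of 0.0170 (1008 pairs) without it, which argues against a general advantage of short spans. No biological explanation was tested.

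More genes were called lower than higher, 2304 against 651. Scaling to the median gene brought the lower share to 46.2%, but such scaling centres the changes by construction, so that this test cannot decide. Displacement by the raised transcripts was examined with totals taken without all genes changed at least 2-fold. The median change was then -0.0239 in place of -0.0942, and 808 genes were higher and 999 lower. This rescaling sets the rest of each library to the same total, which pulls the median towards 0 by construction. It therefore shows how far the shift depends on the totals and cannot decide either. A loss of some mRNAs in absolute terms stays open, because spike-in rows were listed at 0 and TPM carries no absolute scale.

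Long intergenic RNAs were tested for transcription past the ends of upstream genes, which stress can cause. The 59 that start within 20 kb after an expressed coding gene on the same strand had a median change of -0.120. The other 325 had -0.0417, a difference of -0.0786. Of 10000 random label draws, 94.04% gave a difference smaller in size, so its direction is uncertain. The predicted rise was not seen among these annotated RNAs with a mean of at least 1 TPM. Poly-A selection captures transcripts without poly-A tails poorly, so the test cannot decide whether transcription past gene ends occurred.

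Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, gave as many changed genes (2955, highest other 1) and 1 gave as many at least 2-fold changes (186, highest other 1). For the lists, 2 splits called as many (real 16, highest other 18), and each of the 9 others called at least 10. Every other split mixed DMSO and H182 libraries within its groups, so the difference between them widened the spread within groups and held gene calls low. The other splits thus do not stand for an absence of effect, for genes or for lists. All 10 are also too few to give a share under 0.05.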
